A study of Homo sapiens with 10 samples.

How the data were processed

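Total RNA of 4 untransduced lung carcinoma lines and of 6 transduced A549 cultures was measured on one-colour (Cy3) Agilent arrays. Per the labels' protocols, cells grew in medium with 10% serum, retrovirus was collected from packaging cells at 48 and 72 h, cells were collected 96 h after infection, and RNA was amplified with random primers after removal of ribosomal RNA. Per the file headers and the submitters' processing notes, scanned images were read with Agilent Feature Extraction 11.0.1.1. The deposited scanner files give for each spot a background-subtracted and detrended signal intensity, a median pixel intensity with its local background, and flags for outliers, saturation and signal well above background. No scaling between arrays is recorded in the headers. The deposited value table of the authors holds log2 values of 39697 probes. Each of its columns followed the log2 scanner signal of its own array (Pearson's r at least 0.999, slope between 0.96 and 1.05), so that its scale is log2 and its direction that of the signal. Its column medians were 7.65, 7.61, 7.62 and 7.61 for A549, H460, H322 and H3123, 7.65 and 7.66 for vector, 7.66 and 7.66 for LKB1-K78I, and 7.66 and 7.66 for LKB1-wt, and how the authors scaled the columns to each other is not given in the sources used here. All its probes were well above background on at least 4 of the 10 arrays.

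Groups were taken from the labels, which state 2 biological replicates per group. For the LKB1-null and LKB1-wt lines the replicates are different cell lines, so their spread includes every difference between lines. No pair of arrays within a group held near-identical values, and the closest pair, the LKB1-wt arrays, differed by at least 2-fold at 2083 of 41220 probes. Slides were inferred from the scan date in the scanner headers, and no slide identifier was used. All untransduced lines, both vector arrays, LKB1-K78I replicate 1 and LKB1-wt replicate 1 shared a scan date (slide 1). LKB1-K78I replicate 2 and LKB1-wt replicate 2 shared another (slide 2). Slide could therefore be a block in the transduction set and not in the cell lines, which were all on 1 slide.

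Processed signals were averaged over the unflagged spots of a probe, taken to log2, and reduced by the 75th percentile of the array over the 58964 non-control probes. Control spots and spots flagged as outliers were left out, and no probe was saturated. A probe was kept when well above background on every array of at least 1 group of the fit, which left 39571 probes in the transduction set and 38595 in the cell lines. Each set was fitted on its own with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term, two-sided tests, Benjamini-Hochberg adjustment over probes and a threshold of 0.05. The residual degrees of freedom were 3 and 2. Where a probe was not well above background on either array of a group, the fold is given as at least the mean of the brighter group over the mean, across arrays of the dimmer group, of the higher of its own value and the lowest signal well above background. The fit was tested on simulated arrays with 200 changed probes.

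Of the 58964 probes, 20 carry a RefSeq accession in the scanner files, with 10 spots each, and all 20 were matched without version to a table of RefSeq genes of assembly GRCh38.p14, used for names only. The files do not pair the other probes with names. The rule for named genes, written before the data were examined, took STK11, LINC00473 and INSL4 first and then named genes by size of change in each comparison. It could be applied only to these 20 transcripts. The 22 gene lists fixed at the same time were not analysed here, and the overlap of the cell lines with the transduction, planned per gene, was made per probe. At most 2 probe identifiers in each direction are printed, those of lowest p among probes at least 2-fold apart in the cell lines. GAPDH and PGK1 control spots at the 5′ and 3′ ends, chosen as a measure of coverage after the data were seen, were averaged over spots on the log2 scale, and the 5′ minus 3′ difference is free of scaling between arrays.

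Alternatives were quantile normalization, normexp background correction with an offset of 50 followed by the 75th percentile, the authors' value table, no filter, a stricter filter, an intensity trend with a robust prior, 1 fit of all 10 arrays, slide as a block or slide 1 alone, the replicate number as a block, other thresholds and leaving out each array. The median spot intensity stood in for the mean in normexp, since the scanner files held no mean spot intensity. The GAPDH 5′ minus 3′ value as a covariate was added after the data were seen, and for the overlap it was put in the transduction fit alone or in both fits.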

Results

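RNA from lung carcinoma cell lines was hybridised to 10 one-colour microarrays that carry probes for long non-coding RNAs and mRNAs. The study asked which transcripts go with loss of LKB1, the tumour suppressor kinase encoded by STK11. Of these arrays, 4 held untransduced lines, with 1 array each for A549 and H460, which lack LKB1 (LKB1-null), and for H322 and H3123, which carry wild-type LKB1 (LKB1-wt). The other 6 held A549 cells transduced with a pBabe retrovirus and collected 96 h after infection, with 2 biological replicates each of empty vector, the kinase-dead mutant LKB1-K78I and LKB1-wt. Between 63.3% and 70.0% of the 58964 non-control probes lay well above background on an array, and the 75th percentile of the signal ran from 337.9 units in H460 to 656.2 units in H322. The number of arrays limits the precision. The files do not pair 58944 of the probes with gene names, so named genes are limited to 20 transcripts with a RefSeq accession, most of them abundant housekeeping mRNAs, and STK11 itself was not analysed here. Levels below are log2 signal relative to the 75th percentile of the array.

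Among the named transcripts, ODC1 and PGK1 stood furthest apart between the LKB1-null and the LKB1-wt lines. ODC1, which encodes ornithine decarboxylase of polyamine synthesis, had a level of 8.38 ± 0.77 (SD, n = 2) in the LKB1-null lines and 6.33 ± 0.36 (SD, n = 2) in the LKB1-wt lines, 4.15-fold higher without LKB1. PGK1, which encodes the glycolytic enzyme phosphoglycerate kinase, had a level of 1.48 ± 0.24 (SD, n = 2) in the LKB1-null lines and 3.85 ± 1.06 (SD, n = 2) in the LKB1-wt lines, 5.18-fold lower without LKB1. The log2 difference of PGK1 between the lines, -2.37 with all 4, ran from -3.12 without H322 to -1.62 without H3123, and that of ODC1, 2.05 with all 4, from 1.51 without H460 to 2.59 without A549. Neither passed limma's test, with an adjusted p of 0.186 for each when adjusted over the list alone, and of 0.323 and 0.317 over all probes. The PGK1 control spots on the same arrays did not show a difference of that size. The levels of the 3′ spot ran from 8.08 in H322 to 9.21 in A549, with H3123 at 9.05, and those of the 5′ spot were 4.69 in A549 and 5.08 in H460 against 5.01 in H322 and 5.71 in H3123. GRM4, a glutamate receptor, had a level of -3.42 ± 0.04 (SD, n = 2) in the LKB1-null lines and -2.26 ± 1.67 (SD, n = 2) in the LKB1-wt lines, where H322 alone held the difference. The other 17 transcripts, among them ACTB, GAPDH, RPLP1 and RPS18, differed by less than 2-fold, and their direction rested on the scaling, with 16 of all 20 higher in the LKB1-null lines under the main scaling and 8 of 20 under quantile normalization.

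Over all 38595 probes tested in the cell lines, 2 passed an adjusted p of 0.05, both higher in the LKB1-null lines (limma, adjusted p = 0.0297 for each). ASHGA5P042172 was not well above background in either LKB1-wt line and was at least 6270-fold higher in the LKB1-null lines, and ASHGA5P043785 was at least 2810-fold higher in the same sense. These bounds hold for the main scaling, and with normexp the fitted log2 differences were 10.51 and 9.60. Of the probes lower in the LKB1-null lines, ASHGA5P042476 (log2 difference -8.57 ± 0.45, SE) and ASHGA5P019850, at least 99.2-fold lower, had the lowest p and did not pass (limma, adjusted p = 0.0536 for each). At an unadjusted p under 0.05, 4614 probes (12.0%) differed, all by at least 2-fold, with 2026 higher and 2588 lower in the LKB1-null lines. That balance turned without A549 (2560 higher, 2058 lower) and without H460 (3820 higher, 3029 lower), and with the 5′ minus 3′ difference of the GAPDH control spots as a covariate (1324 higher, 1216 lower). In data simulated with this spread, 4.93% of unchanged probes met that limit and 83.6% of probes changed by 2 on the log2 scale did. No probe changed by 4 or less passed the adjusted threshold there. The simulation changed 200 probes, whereas 33.2% of probes were at least 2-fold apart between these lines. The adjusted threshold depends on that share, so the simulated recovery does not give the power of this comparison. The count at the adjusted p was 606 without A549, 722 without H460, and 0 without either LKB1-wt line, 2871 when all 10 arrays shared 1 estimate of the spread, and 0 with normexp background correction, the authors' value table, a filter that keeps only probes well above background on every array, or the GAPDH covariate. The difference between GAPDH control spots at the 5′ and 3′ ends of the transcript, taken here as a measure of RNA coverage, also separated the groups. It was -0.60 ± 0.09 (SD, n = 2) in the LKB1-null lines and 0.05 ± 0.02 (SD, n = 2) in the LKB1-wt lines. The 75th percentile of the signal separated them too, at 393.4 and 337.9 units against 656.2 and 447 units. Coverage and labelling yield were therefore not separated in the lines.

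**Figure D1:**
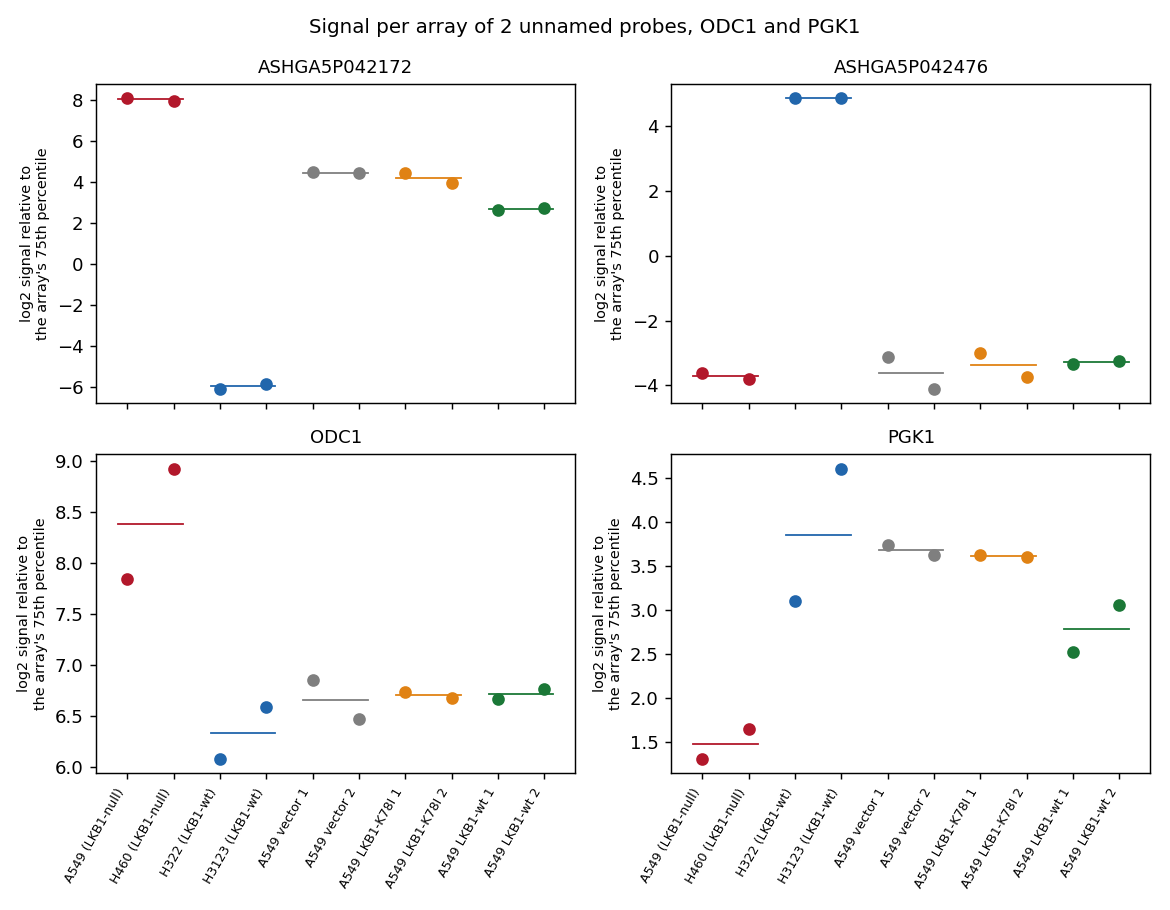
Level of 2 unnamed probes and of ODC1 and PGK1 on each of the 10 arrays, as log2 signal relative to the array's 75th percentile, with a point per array and a line at the mean of each group. ASHGA5P042172 had a mean of 8.02 in the LKB1-null lines, -5.95 in the LKB1-wt lines, 4.45 in A549 with vector and 2.68 in A549 with LKB1-wt.

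In A549 cells, LKB1-wt was set against the empty vector to ask which transcripts respond to restored LKB1. PGK1 had a level of 2.79 ± 0.37 (SD, n = 2) with LKB1-wt and 3.68 ± 0.08 (SD, n = 2) with vector, a log2 difference of -0.89 ± 0.24 (SE) that did not pass correction over the 20 transcripts (limma, adjusted p = 0.228). The PGK1 control spots did not follow it, since the 3′ spot had levels of 8.91 and 8.88 with LKB1-wt against 9.03 and 8.44 with vector, and the 5′ spot 5.40 and 5.27 against 4.73 and 5.69. The other 19 transcripts, ODC1 among them with levels of 6.71 ± 0.07 (SD, n = 2) and 6.65 ± 0.27 (SD, n = 2), lay within 0.5 on the log2 scale. ASHGA5P042172, the probe of lowest p in the cell lines, had a level of 2.68 ± 0.04 (SD, n = 2) with LKB1-wt against 4.45 ± 0.02 (SD, n = 2) with vector. Its log2 difference was -1.77 (limma, unadjusted p = 3.79e-04, adjusted p = 0.883 over all probes). ASHGA5P043785, the other probe that passed in the cell lines, had a log2 difference of -0.42 (limma, unadjusted p = 0.126, adjusted p = 0.958 over all probes). Over 39571 probes, none passed an adjusted p of 0.05 by limma, and 1911 (4.83%) had an unadjusted p under 0.05. Of these, 588 changed by at least 2-fold, 198 higher and 390 lower with LKB1-wt. That is 1.49% of the probes, where simulated unchanged probes met the same limit in 1.40% of cases. The simulation gave a probe the same spread in all groups. On the real arrays the vector pair was at least 2-fold apart at 5717 probes, against 2826 for LKB1-K78I and 1716 for LKB1-wt. In the same fit LKB1-K78I against vector reached 0.541%. The simulated 1.40% is therefore not a null rate for these arrays and does not show that the count is at noise level. In the same simulation 46.3% of probes changed by 2 on the log2 scale and 93.9% of those changed by 4 passed the adjusted threshold. The count of 588 became 2648 without vector replicate 1, 2291 without vector replicate 2 and 1134 without LKB1-wt replicate 2. The balance of directions turned, with 1735 higher and 913 lower without vector replicate 1, 1402 and 889 without vector replicate 2, 455 and 395 without LKB1-K78I replicate 1, and 837 and 436 with the GAPDH 5′ minus 3′ value as a covariate. On slide 1 alone, where LKB1-wt had 1 array and the spread came from the 2 vector arrays only, it was 1542, with 1069 higher and 473 lower. The vector arrays had GAPDH 5′ minus 3′ values of -0.64 and 0.13, on either side of the LKB1-wt arrays at -0.51 and -0.45, and lay at -79.8 and 77.8 on the first principal component of the 6 arrays, which held 38.3% of the variance.

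**Figure D2:**
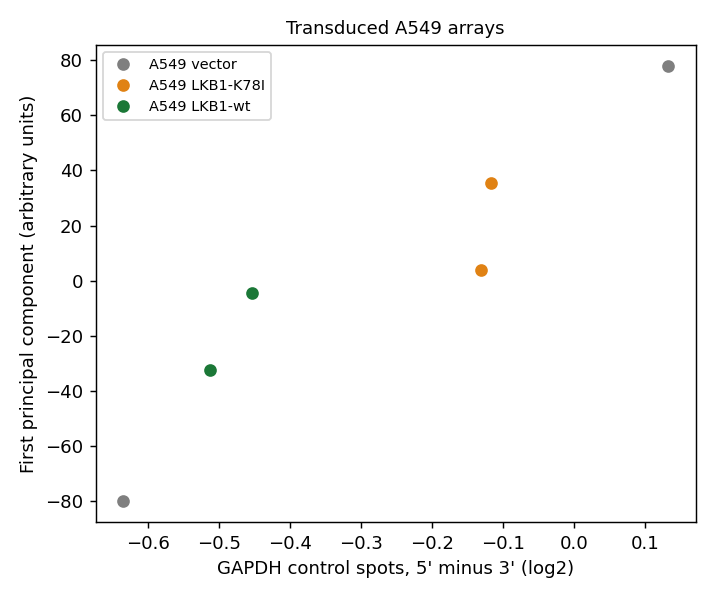
First principal component of the 6 transduced A549 arrays, in arbitrary units, against the log2 difference of the GAPDH control spots at the 5′ and 3′ ends, with a point per array. The vector arrays lie at both ends, at -0.64 and 0.13 on the horizontal axis, with the other 4 arrays between them.

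LKB1-K78I was set against vector to show what the construct does without kinase activity. All 20 named transcripts lay within 0.5 on the log2 scale, and PGK1 had a level of 3.61 ± 0.01 (SD, n = 2) with LKB1-K78I against 3.68 ± 0.08 (SD, n = 2) with vector. ASHGA5P042172 had a level of 4.19 ± 0.34 (SD, n = 2), a log2 difference of -0.25 from vector, and ASHGA5P043785 had a log2 difference of -0.05. No probe passed an adjusted p of 0.05 by limma, 628 (1.59%) had an unadjusted p under 0.05, and 214 of these changed by at least 2-fold, 83 higher and 131 lower. With slide as a block there were 368. On slide 1 alone, where LKB1-K78I had 1 array and the spread came from the vector arrays only, there were 800, with 434 higher and 366 lower. The count was 1648 without vector replicate 1, 2842 without vector replicate 2, 1807 without LKB1-K78I replicate 1 and 831 without LKB1-K78I replicate 2. The balance of directions turned in each of these, with 1238 higher and 410 lower, 1962 and 880, 1054 and 753, and 427 and 404, and it was 665 and 131 with the GAPDH 5′ minus 3′ value as a covariate. Both comparisons use the same vector arrays. Across 39571 probes, which are not independent replicates, the log2 changes of LKB1-wt and of LKB1-K78I against vector correlated at r = 0.576, where simulated unchanged groups gave 0.499. Their covariance was 0.105 against a simulated 0.0724. With no shared array, LKB1-wt against vector replicate 1 and LKB1-K78I against vector replicate 2 gave a covariance of -0.0091, and the reverse assignment -0.107. A difference between the vector arrays lowers the covariance over these 2 assignments, whatever the constructs do. These arrays lay at -79.8 and 77.8 on the first principal component. The simulation gave a probe the same spread in all groups. Neither comparison can therefore tell whether the constructs share an effect.

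LKB1-wt against LKB1-K78I asked for the effect of kinase activity with a construct in both groups. PGK1 had a log2 difference of -0.82 ± 0.24 (SE; limma, adjusted p = 0.314 over the 20 transcripts), and its levels did not overlap between the groups. Its control spots went different ways, with the 3′ spot at 8.91 and 8.88 with LKB1-wt against 8.65 and 8.63 with LKB1-K78I, and the 5′ spot at 5.40 and 5.27 against 5.54 and 5.63. The other named transcripts differed by less than 2-fold, with 19 of 20 higher with LKB1-wt under the main scaling and 11 of 20 under quantile normalization. ASHGA5P042172 had a log2 difference of -1.51 (limma, unadjusted p = 8.16e-04, adjusted p = 0.981 over all probes). ASHGA5P043785 had a log2 difference of -0.38 (limma, unadjusted p = 0.163). No probe passed an adjusted p of 0.05 by limma, 1301 (3.29%) had an unadjusted p under 0.05, and 458 of these changed by at least 2-fold, 159 higher and 299 lower with LKB1-wt. Each slide held 1 array of LKB1-wt and 1 of LKB1-K78I, so the comparison could be made within slides, where 2709 of 41220 probes on slide 1 and 2731 on slide 2 differed by at least 2-fold between single arrays. With slide as a block 558 probes were past the unadjusted limit and none past the adjusted one. The count of 458 was 1322 without LKB1-K78I replicate 1, 1371 without LKB1-K78I replicate 2 and 837 without LKB1-wt replicate 2. The balance of directions turned in each, with 809 higher and 513 lower, 697 and 674, and 420 and 417. On slide 1 alone, 1 array against 1 with the spread taken from the vector arrays, it was 1823, with 1239 higher and 584 lower. The GAPDH 5′ minus 3′ value was -0.48 ± 0.04 (SD, n = 2) with LKB1-wt and -0.12 ± 0.01 (SD, n = 2) with LKB1-K78I, also without overlap.

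The last comparison asked whether the transduction moved the transcripts that differ between the lines, and it was made per probe. At the adjusted threshold no probe was shared, since the transduction gave none. At an unadjusted p under 0.05 with at least 2-fold, over 36946 probes tested in both sets, 31 were higher in the LKB1-null lines and lower with LKB1-wt than with vector, where independent lists would share 16.3 (one-sided Fisher's exact test over probes, which are not independent, p = 5e-04). ASHGA5P043785 was not among them. ASHGA5P042172 was 1 of them, but it was also lower with vector, at 4.46 and 4.43, than on the 1 array of untransduced A549, at 8.08. With normexp 11 such probes were found (one-sided Fisher's exact test, p = 0.0522) and with the stricter filter 16 (p = 0.0766), whereas with the GAPDH 5′ minus 3′ value as a covariate there were 34 against 17.6 with it in the transduction fit alone (p = 2.14e-04) and 43 against 11.3 with it in both fits (p = 7.21e-14). In the opposite sense 4 probes were lower in the LKB1-null lines and higher with LKB1-wt, against 6.41 for independent lists. With the covariate in the transduction fit alone 100 were, against 42.9 (one-sided Fisher's exact test, p = 2.9e-15), and with it in both fits 31, against 22.3 (p = 0.0418). Probes higher in the LKB1-null lines and also higher with LKB1-wt, a sense that runs against LKB1 status, numbered 4 against 5.5. With the covariate in both fits they numbered 54 against 23.6 (one-sided Fisher's exact test, p = 1.9e-08). The GAPDH value separated the LKB1-null from the LKB1-wt lines, so that fit cannot tell coverage from LKB1 status. A larger group of 120 probes was lower in the LKB1-null lines and also lower with LKB1-wt in A549, against 19 for independent lists (one-sided Fisher's exact test, p = 9.59e-64). With the GAPDH covariate in the transduction fit alone there were 105 against 20.6, and with it in both fits 16 against 10.7 (one-sided Fisher's exact test, p = 0.0718). With slide as a block the 31 stayed at 31 in number and the 120 became 123. The sum over both opposite senses was 35, against 22.7 for independent lists. It was 55 against 32.8 without H460 and 59 against 38.1 without LKB1-wt replicate 2. Without vector replicate 1, which left 1 vector array, the sum fell short of independent lists, as did probes lower in the LKB1-null lines and higher with LKB1-wt. Those higher in the LKB1-null lines and lower with LKB1-wt exceeded independent lists there. So did those higher in the LKB1-null lines and higher with LKB1-wt, unlike with all arrays. Without vector replicate 2 the sum was 228 against 98.4, of which 188 were lower in the LKB1-null lines and higher with LKB1-wt. The count of 120 was 201 against 34.9 without vector replicate 1 and 78 against 17.1 without LKB1-wt replicate 1.

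**Figure D3:**
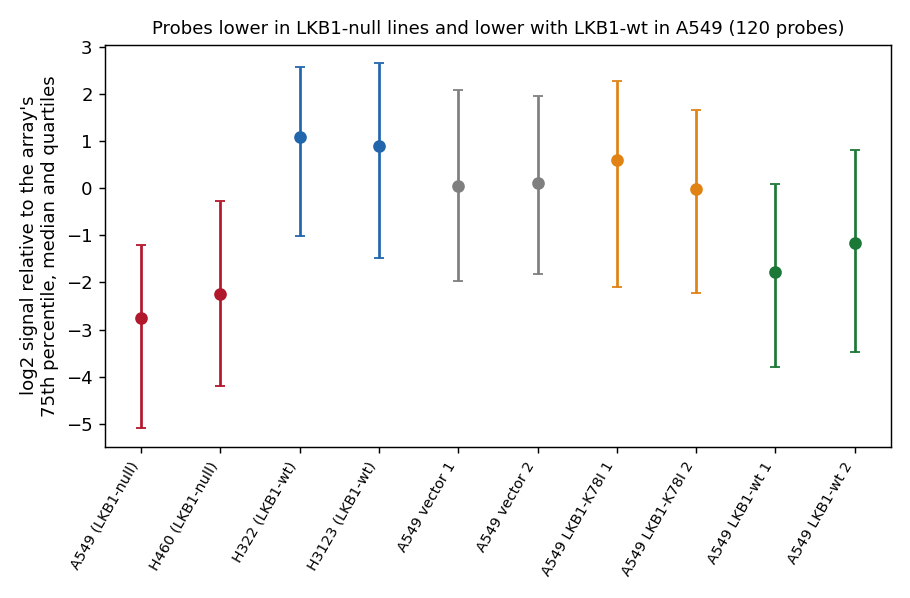
Level of the 120 probes that were lower in the LKB1-null lines and lower with LKB1-wt, as median and quartiles over probes on each of the 10 arrays, in log2 signal relative to the array's 75th percentile. The medians were -2.75 in untransduced A549 and -2.24 in H460, 1.08 in H322, 0.05 and 0.11 with vector, and -1.78 and -1.17 with LKB1-wt.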

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

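The tests of scaling, mixture with other lines, kinase activity and the GAPDH covariate in both fits were chosen after the results they bear on had been seen, and the test with that covariate in the transduction fit before its result.

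Relative to LKB1 status, 120 probes went opposite ways in the cell lines and in A549. Both LKB1-null lines lay below both LKB1-wt lines, and both LKB1-wt arrays of A549 below both vector arrays. Each was past the unadjusted limma limit with 2-fold in both sets and none past correction in A549. The difference between the 2 sets itself was not tested. The median level of the 120 was -2.75 on the 1 array of untransduced A549, 0.0539 and 0.11 with vector, and 0.593 and -0.0235 with LKB1-K78I. On these probes, transduced A549 without active LKB1 thus lay nearer to the LKB1-wt lines, at 1.08 and 0.895, than to untransduced A549. With LKB1-wt the medians were -1.78 and -1.17, still above untransduced A549. The probes were chosen as low in untransduced A549, high in the LKB1-wt lines and higher with vector than with LKB1-wt, which favours such an order. The rise from untransduced A549 was not tested. Over 41220 probes, vector 1 had a Pearson's r of 0.942 with untransduced A549, against 0.850 with H322 and 0.872 with H3123. For vector 2 these were 0.919, 0.886 and 0.882. Array scaling is argued against, since quantile normalization gave 132 such probes against 22.7 for independent lists. RNA of the LKB1-wt lines in the vector samples is argued against, since 183 probes bright in those lines and off in untransduced A549 showed a median share of 0.0244 of those lines' signal in vector 1 (upper quartile 0.247), where the 120 probes had 0.55, and 0.0293 (upper quartile 0.446) against 0.54 in vector 2. For uneven RNA coverage, the GAPDH 5′ minus 3′ value as a covariate in the A549 fit gave 105 such probes against 20.6. The median change of the 120 was -1.37 in place of -1.39, and 89 of them stayed past the limit. Within groups that value varied mostly between the vector arrays (SD 0.54, against 0.01 for LKB1-K78I and 0.04 for LKB1-wt). The choice of the 120 favoured probes alike on the vector arrays, so the covariate could hardly move their median. The count shows only that the overlap did not depend on a linear effect of the GAPDH value in A549. With the covariate in both fits 16 were found against 10.7. The median difference between the lines then went from -3.01 (median SE 0.65) to 0.59 (median SE 4.35). Coverage and LKB1 status cannot be told apart in the lines because the GAPDH value separates them. LKB1 kinase activity may be involved as a hypothesis, since the median of LKB1-wt minus LKB1-K78I was -1.42 over these probes. The shift was not particular to them. The 31 probes higher in the LKB1-null lines and lower with LKB1-wt had a median of -1.03. Noise in the shared LKB1-wt arrays alone would carry over -0.694, if their spread equalled that of the vector arrays. A shift of the LKB1-wt arrays from another source would carry over in full. The GAPDH value also separated LKB1-wt (-0.48) from LKB1-K78I (-0.12), so coverage stays open there too. Coverage, above all in the cell lines, stays open, as do infection, culture and other differences between lines, which were not tested.

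In data outside the comparisons, 3 of the 60 negative control designs were well above background on all 10 arrays, the brightest with a median signal of 165 units against 4.59 units for the other kind of negative control spot.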

How the results depend on the processing

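The GAPDH covariate was chosen after the data were seen, and for the overlap also the trend and the slide block. The adjusted threshold gave 0 probes in all 3 transduction comparisons under every setting that kept all arrays, and 0 to 1 when an array was left out. The cell lines gave 2 probes, 0 with normexp, the authors' table, the stricter filter or the covariate, 2871 with all arrays in 1 fit, and 0 to 722 with an array left out, where the lone array is assumed to vary like the others. The unadjusted limit with 2-fold gave 588 for LKB1-wt and 214 for LKB1-K78I against vector, 458 between them and 4614 in the cell lines. In the order of the first 3, normexp gave 187, 35 and 177, the stricter filter 374, 57 and 286, no filter 1148, 638 and 820, and the covariate 1273, 796 and 1081. One fit of all arrays gave 342 and 246 in the first and last of these and 8415 in the cell lines, where the covariate gave 2540. The overlap of 35 was 11 with normexp, 16 with the stricter filter, 61 without filter, 134 with the covariate in the transduction fit alone (100 of them lower in the LKB1-null lines and higher with LKB1-wt), 74 with it in both fits, and 35 to 228 with an array left out. For that overlap independent lists would share 22.7 in the main setting, 7.55 with normexp, 15.3 with the stricter filter and 48.8 without filter. They would share 60.5 with the covariate in the transduction fit alone and 33.6 with it in both fits. The 120 probes lower in both, against 19 for independent lists, became 61 against 8.19 with normexp. With the covariate in both fits they became 16 against 10.7. GRM4 had log2 differences of -2.35 to 0.020 with an array left out, the last without H322. Causes were not tested.

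Replicate numbers were not shown to pair the cultures, since deviations of same-numbered arrays correlated at 0.17, 0.22 and -0.0043. With the replicate number as a block the adjusted counts were 0 in the 3 transduction comparisons, the unadjusted ones 643, 293 and 530, and the overlap 39. The gene list tests and the named genes without an accession were not run, nor the value table for the 20 transcripts, which it does not hold. Dim probes set the unadjusted counts in part, since 175, 116, 124 and 904 of the 588, 214, 458 and 4614 were not well above background in the lower group.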

Other observations

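The tests in this part were chosen after the results had been seen.

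Untransduced A549 stood apart from A549 with vector. It differed by at least 2-fold from vector replicate 1 at 9712 of 41220 probes (23.6%) and from vector replicate 2 at 12988 (31.5%), whereas the vector arrays differed from each other at 6091 (14.8%). PGK1 had a level of 1.31 in untransduced A549 and 3.74 and 3.62 with vector, whereas its 3′ control spot had 9.21 against 9.03 and 8.44 and its 5′ control spot 4.69 against 4.73 and 5.69. ODC1 had a level of 7.84 in untransduced A549 and of 6.84 and 6.46 with vector. Untransduced A549 had 1 array, so these values have no replicate check.

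The vector arrays were the farthest apart of the 6 transduced arrays on the first principal component, which held 38.3% of the variance, and differed by at least 2-fold at 5717 of 39571 probes against 2826 for LKB1-K78I and 1716 for LKB1-wt. Scaling is argued against, since quantile normalization left 5577 of them apart in number. Slide, as inferred from the scan date, is argued against, since both were on slide 1 with a gap of 158 units against 23.0 between slide means. The component followed the GAPDH 5′ minus 3′ value over the 6 arrays (Pearson's r = 0.944, exact permutation p = 0.00278, adjusted 0.00556 over 4 relations; Spearman's rho = 1.00, exact permutation p = 0.00278, adjusted 0.00556; r = 0.844 without the vector arrays). That makes uneven RNA coverage a candidate explanation, but the same value followed the 75th percentile of the signal (Pearson's r = 0.993, exact permutation p = 0.00139, adjusted 0.00556; Spearman's rho = 1.00, exact permutation p = 0.00278; r = 0.984 without the vector arrays), so coverage and labelling yield were not separated. No biological explanation was tested, since both arrays belong to 1 group.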
